A study of Mus musculus with 8 samples.

How the data were processed

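RNA from mouse liver was measured on 8 1-colour Agilent expression arrays, 4 of samples given an adenovirus labelled AdLeXis and 4 of samples given one labelled AdGFP. Per the labels' protocols, the mice were of the bl6 strain, 12 weeks old and on chow, and RNA was taken on day 6. The titles, the treatment tag and the series design name AdLeXis and AdGFP, whereas the treatment text in the labels names a control vector and a vector against Raly; samples were grouped by the treatment tag. The names of the deposited files carry other sample numbers than the titles; replicate numbers are those of the titles. The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

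The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.5.1.1 per the file headers. Per the file headers, the processed intensity was background-subtracted and detrended within each array and was not scaled between arrays. The deposited value table of the series holds the same processed intensity to within a relative difference of 0 on all 8 arrays, so using it changes nothing; its scale is linear and no centring had been applied, and its column medians ran from 12.7 to 27.7 over all features. Probe coordinates are those of mouse build mm9 per the file headers. Flags for spots well above background, saturated spots and outlier spots were taken from the same files, as deposited.

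Each array held 59305 spots of 55681 different non-control probes. The log2 of the processed signal was scaled by subtracting each array's 75th percentile over non-control spots, then adding back the mean over arrays. Control spots and outlier spots (127 to 256 per array) were left out, and spots of one probe were averaged on the log2 scale. A probe was kept when it was well above background on at least 4 arrays and measured on at least 2 arrays of each group, which left 34436 probes. Each gene was represented by its kept probe with the highest mean over all arrays, which gave 23981 genes. Different kept probes of 1 gene passed the test in opposite directions for 16 genes. Names in the files were updated through RefSeq accessions in a gene table of assembly GRCm38.p6, which was used for names and the order of neighbouring genes only: 27732 probes were named by accession, 3352 by symbol, and 24597 kept the name in the files.

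Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the one term, two-sided, and Benjamini-Hochberg adjustment over all genes tested. Adjusted p-values below are from this test unless another is named, and the threshold was 0.05. The 31 gene lists were written from textbook knowledge before the data were examined. They were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 31 lists. Genes that another list also holds numbered 5 for other SREBP-2 targets, 6 for LXR targets, 9 for pericentral genes, 4 for hepatocyte markers and 0 for the interferon and T cell lists. Camera with an estimated correlation, rank-based camera and fry were run beside it. The mean over a list on each array was compared by an exact permutation test over 70 relabellings, two-sided, whose smallest possible p is 0.0286. A gene with no probe well above background on any array of a group has only a bound there: the other group's mean was set against the mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal, and the ratio is given as at least N-fold.

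Genes are named by a rule written before the data were examined: the probes within 300 kb of the Abca1 probe, with Abca1 and Raly; the 10 largest rises and 10 largest falls among genes past the threshold whose 4 AdLeXis arrays all lay on one side of all 4 AdGFP arrays, leaving out names that are identifiers only; up to 4 members of smallest p for each list described, up to 8 for cholesterol biosynthesis; single cholesterol genes, among them Hmgcs1, Sqle and Srebf2; and, where examples are given for a list that did not pass, the 2 of its 10 brightest members nearest to no change. Some genes that the rule selects are counted in their lists but not reported by name. Genes named outside the rule are said to have been chosen after their values were seen. Before the data were examined it was thought that the array name AI427809 might stand for LeXis; the gene table gives it as a synonym of Mexis, a different transcript.

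The fit and the list tests were tested on simulated data for this comparison, with the means and spreads of 23981 genes and known folds given to some of them. Of the genes changed 1.5-fold, 27 of 67 were recovered in the right direction, of those changed 2-fold, 47 of 67, and of those changed 4-fold, 61 of 66. In the same run 6 unchanged genes were called. The cholesterol biosynthesis list was lowered 1.5-fold in that run, and 1 of 31 lists was called. With no gene changed, 0 genes and 0 lists were called. Genes were drawn independently of each other, whereas the estimated correlation within the cholesterol biosynthesis list was 0.68 in the data. The run therefore does not test false list calls among correlated genes. Far fewer genes were changed in the run than were called in the data. The adjusted p depends on that share, so the recovery rates may not hold for the data.

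All 8 arrays lay on 1 slide and came from 1 scan, so no slide or scan block could be fitted. Every AdGFP array lay in row 1 of the slide and every AdLeXis array in row 2, so slide row and group cannot be told apart. Alternatives were other scalings (median, quantile, normexp with an offset of 50 and quantile, and cyclic loess, the last chosen after seeing the data), other filters on dim probes, the mean of a gene's probes or each probe on its own, outlier spots kept, other variance models, a replicate block of the title number, and each array left out in turn. The number of arrays limits the precision.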

Results

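Liver samples given an adenovirus carrying LeXis, a long non-coding RNA transcribed beside the cholesterol efflux gene Abca1, were compared with liver samples given a GFP adenovirus, 4 arrays in each group. The comparison asks which liver transcripts change when LeXis is raised. The AdLeXis arrays were brighter before scaling: the 75th percentile of the processed intensity ran from 381 to 448 on AdLeXis arrays and from 220 to 297 on AdGFP arrays, and 62.6% to 67.7% against 58.9% to 62.5% of spots were well above background. No spot was saturated (0 on each array). After scaling, arrays of one group correlated at 0.991 to 0.994 and arrays of different groups at 0.981 to 0.989 across genes, which are not independent replicates. The first principal component held 42.6% of the variance and separated the groups.

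No probe carries the name LeXis in the files. In the gene table, Lexis1 is the neighbour of Abca1 on the side of Mexis. The table is of a later mouse build than the probe coordinates, so no probe was matched to Lexis1 by position. On the array, 3 reverse-strand probes for a lincRNA region on chromosome 4 (mm9, 53217935 to 53230433), between the probes for Abca1 and for AI427809 (Mexis), rose on all 4 AdLeXis arrays. Probe A_30_P01022419 (53218021 to 53218080) was not well above background on any AdGFP array and stood at 10.49 ± 0.40 (SD, n = 4) on the log2 scale in AdLeXis, at least 206-fold higher (limma adjusted p = 4.91e-06 over all probes). Probe A_30_P01028022 (53219839 to 53219898) went from 2.58 ± 1.21 to 9.95 ± 0.36 (SD, n = 4 per group; limma adjusted p = 0.00192 over all probes) and A_30_P01024243 (53217961 to 53218020) from 1.52 ± 1.74 to 9.70 ± 0.44 (SD, n = 4 per group; limma adjusted p = 0.00358 over all probes), each well above background on 1 of 4 AdGFP arrays. The difference of 7.37 for A_30_P01028022 was 4.55 under normexp scaling, whose offset shrinks changes of dim probes. The other named transcript inside the region, 4930412L05Rik, and the neighbouring 4930522O17Rik were not well above background on any array. Mexis itself gave a log2 difference of 0.22 (SE 0.13, limma adjusted p = 0.293).

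**Figure D1:**
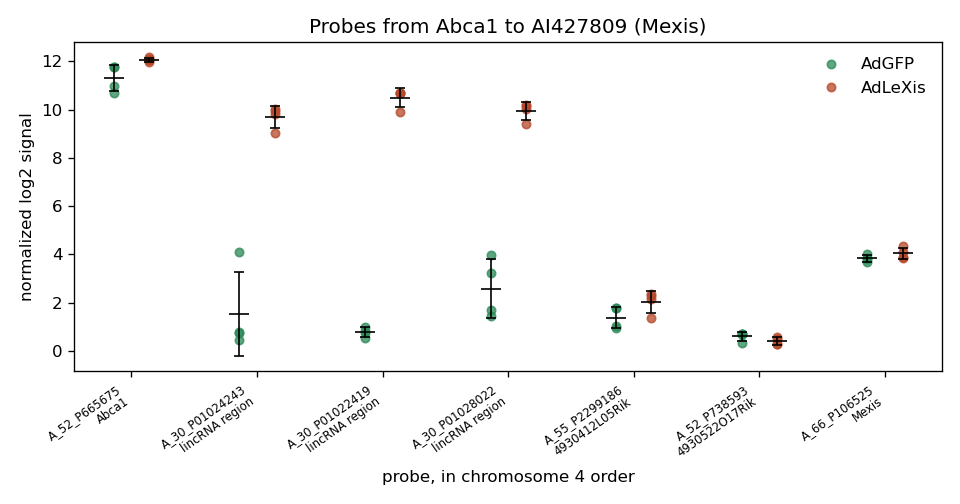
Normalized log2 signal (y axis) of the probes from Abca1 to AI427809 (Mexis), in chromosome 4 order (x axis), with 1 point per array and the mean and SD of each group of 4. The 3 lincRNA probes stand at means of 9.70 to 10.49 in AdLeXis, above every AdGFP array.

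Abca1, the cholesterol efflux transporter at the same locus, was 0.77 higher on the log2 scale in AdLeXis (SE 0.24) and missed the threshold (limma adjusted p = 0.0630), although all 4 AdLeXis arrays lay above all 4 AdGFP arrays. It passed under 6 alternatives, among them the fits without AdGFP replicate 2 (0.93, adjusted p = 0.0448) and without AdGFP replicate 3 (0.93, adjusted p = 0.0451). Raly, the gene that the treatment text in the labels names, gave 11.46 ± 0.20 in AdGFP and 11.63 ± 0.11 in AdLeXis (SD, n = 4 per group; limma adjusted p = 0.358), and the rise of the lincRNA probes follows the AdLeXis and AdGFP labels.

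Across the transcriptome, 4196 of 23981 genes (17.5%) differed between the groups at an adjusted p under 0.05 (limma), 2095 higher and 2101 lower in AdLeXis. At least a 2-fold change was seen for 473 of the higher and 253 of the lower genes. Detection differed between the directions: 73 higher genes were not well above background on any AdGFP array, and 2 lower genes on any AdLeXis array. With the arrays scaled on their medians the split was 1156 higher and 2676 lower. Of the called genes, 554 higher and 552 lower ones carry only an identifier as a name. The 4 arrays of one group lay on one side of the other 4 for 24.7% of genes, where chance gives 2.86%. Leaving out AdLeXis replicate 4 left 2513 genes (1245 higher, 1268 lower). The lower count was 1358 without AdGFP replicate 1 and 1384 without AdGFP replicate 2, and the higher count was 1360 without AdLeXis replicate 2.

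Among the largest rises, Obp2a, an odorant-binding lipocalin, rose by 5.11 on the log2 scale (SE 0.60, limma adjusted p = 0.00170), and Cox6b2, a testis isoform of a cytochrome c oxidase subunit, rose from 6.62 ± 0.89 to 10.97 ± 0.35 (SD, n = 4 per group; limma adjusted p = 7.54e-04). Smcp, a sperm mitochondrial protein gene, rose by 4.32, Glod5 by 4.25, Wfdc12 by 4.09 and Cfap53, a cilium gene, by 3.93. H19, an imprinted non-coding RNA, rose by 3.67 (SE 0.40, limma adjusted p = 0.00134), although its 6 kept probes ran from -0.29 to 3.77. Obp2a, Smcp and Cfap53 were well above background on 2 of 4 AdGFP arrays, Glod5 on 1 and H19 on 3. The retinol carrier gene Rbp7, the adrenergic receptor gene Adra2a and Wfdc16 were not well above background on any AdGFP array, and were at least 16.2-fold, 5.98-fold and 15-fold higher (limma adjusted p = 1.67e-04, 1.84e-04 and 9.70e-04). Under normexp scaling Obp2a gave 2.48, Smcp 1.87, Glod5 1.17, Cfap53 1.61, H19 1.48, Rbp7 1.43, Adra2a 0.84 and Wfdc16 1.36 on the log2 scale, all still called. H19 gave 2.06 with the mean of its probes.

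Among the largest falls, Fabp5, a fatty acid-binding protein gene, fell by 2.01 (SE 0.17, limma adjusted p = 5.19e-04), from 14.01 ± 0.25 to 12.00 ± 0.29 (SD, n = 4 per group). The chemokine genes Ccl7 and Cxcl9 changed by -1.85 and -1.84, Ch25h, which makes cholesterol hydroxylated on its side chain, by -1.85, and Tubb2a, a tubulin gene, by -1.84. Ly6i changed by -1.84, Oasl2 by -1.80, Masp1, of the lectin complement pathway, by -1.78, and Adh7 by -1.72. The 3 kept probes of Masp1 ran from -2.08 to 0.06. Under normexp scaling Ch25h gave -1.06, Ly6i -0.96 and Adh7 -0.80, still called. Pls1 fell by 1.92 (limma adjusted p = 0.0434) at low signal, well above background on 1 of 4 AdLeXis arrays. Its call was lost under cyclic loess, without any 1 AdGFP array and without AdLeXis replicate 2 or 4, and it gave 0.60 with no filter on dim probes.

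Genes of cholesterol biosynthesis fell together. Of 20 enzymes measured, 14 were lower in AdLeXis, 0 were higher and 6 did not pass (15 lower adjusted over the list alone), with a median log2 change of -0.80 (camera adjusted p = 1.89e-08; adjusted p = 0.341 with an estimated correlation). Squalene epoxidase Sqle fell by 1.29 (SE 0.18, limma adjusted p = 0.00319), farnesyl diphosphate synthase Fdps changed by -1.24 (SE 0.15), Hsd17b7 by -1.22 (SE 0.16) and lanosterol demethylase Cyp51 by -1.10 (SE 0.15). Pmvk, Lss, Idi1 and Nsdhl changed by -0.90, -0.88, -0.80 and -0.76, the last not called under normexp scaling. Hmgcs1 gave -0.39 (SE 0.17, limma adjusted p = 0.149) and was called under normexp scaling (-0.50, adjusted p = 0.0496). The list's mean per array went from 12.51 ± 0.20 to 11.80 ± 0.22 (SD, n = 4 per group; exact permutation p = 0.0286, the smallest possible). The list kept its direction under every scaling tried.

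**Figure D2:**
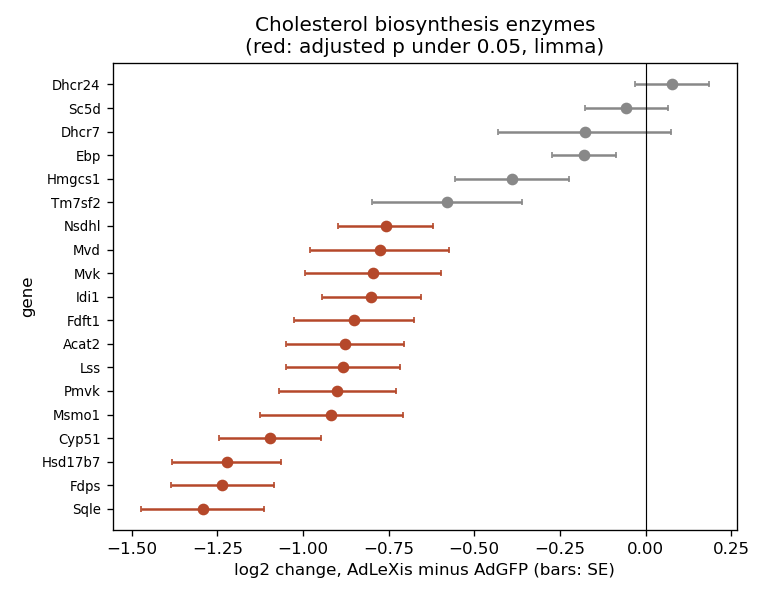
Log2 change, AdLeXis minus AdGFP (x axis, bars are SE from limma), for 19 of the 20 cholesterol biosynthesis enzymes (y axis). The 13 genes in red passed an adjusted p of 0.05, from Sqle at -1.29 to Nsdhl at -0.76.

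Among the 15 other targets of the sterol regulator SREBP-2, 5 were lower and 0 higher (8 lower and 1 higher adjusted over the list alone; median -0.30, camera adjusted p = 0.0112; adjusted p = 0.356 with an estimated correlation). Rdh11 changed by -0.54 (SE 0.11, limma adjusted p = 0.0135), Acss2, which makes acetyl-CoA from acetate, by -0.71 (-1.12 on its other kept probe) and the desaturase gene Fads1 by -0.60. Acss2 lost its call without each array but AdLeXis replicate 1, Fads1 was not called without AdGFP replicate 1, 2 or 3 or AdLeXis replicate 1 or 4, and the list had 2 lower genes without AdGFP replicate 1, 2 or 3 or AdLeXis replicate 4 and 3 without AdLeXis replicate 1 or 3. Srebf2, which encodes SREBP-2, gave -0.22 (SE 0.11, limma adjusted p = 0.227) and was called under normexp scaling (-0.33, adjusted p = 0.0324). Of 17 LXR targets, 6 were lower and 0 higher (6 and 1 adjusted over the list alone; median -0.17, camera adjusted p = 0.0253; adjusted p = 0.341 with an estimated correlation). Pltp changed by -1.01, the desaturase gene Scd1 by -0.82, Apoc1 by -0.55 and Apoe by -0.48, though Apoe gave 0.028 and 0.082 under quantile and normexp scaling and -0.32 under cyclic loess, and Apoc1 lost its call under both. Abca1, at 0.77, was the 1 higher LXR target adjusted over the list alone. The LXR list was not called under quantile (adjusted p = 0.233), normexp (0.678) or loess scaling (0.0691), nor without AdGFP replicate 1 (0.0914). Of 23 genes of fatty acid and triglyceride synthesis, 6 were lower and 2 higher (7 and 2 adjusted over the list alone), and the list did not pass (median -0.20, camera adjusted p = 0.264). Fasn fell by 0.50, and Dgat1, which makes triglyceride, rose by 0.71 (SE 0.10, limma adjusted p = 0.00369). Nearest to no change among the brightest members were Acaca (-0.00084, but 0.25 under normexp scaling) and Acly (-0.020). Fasn was not called without AdGFP replicate 1, 2 or 4 or AdLeXis replicate 2 or 4. The 6 lower genes of this list became 1 without AdGFP replicate 1 or 2, 2 without AdGFP replicate 3 or AdLeXis replicate 4, and 3 without AdGFP replicate 4 or AdLeXis replicate 2. The 2 higher genes became 1 without AdGFP replicate 2 or 3 or AdLeXis replicate 2, 3 or 4, and 3 without AdLeXis replicate 1.

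Interferon-stimulated genes were lower in AdLeXis. Of 45 measured, 36 fell and 0 rose (42 lower adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.56e-20; adjusted p = 0.307 with an estimated correlation). The list's mean per array went from 12.72 ± 0.10 to 11.82 ± 0.27 (SD, n = 4 per group; exact permutation p = 0.0286). The chemokine gene Cxcl9 fell from 14.93 ± 0.19 to 13.08 ± 0.18 (SD, n = 4 per group; limma adjusted p = 3.26e-04). Oasl2, Oas1a, an oligoadenylate synthetase gene, and Psmb8, of the immunoproteasome, changed by -1.80, -1.06 and -1.02. Markers of T cells and natural killer cells fell too: 20 of 24 were lower and 0 higher (20 and 1 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 6.15e-14; adjusted p = 0.0966 with an estimated correlation). Il2rb fell by 1.21, and the granule gene Nkg7, Cxcr6 and perforin, Prf1, changed by -1.09, -1.08 and -1.04 (limma adjusted p from 5.19e-04 to 9.21e-04). Both lists kept their direction under every scaling tried.

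Of 18 Kupffer cell and macrophage markers, 9 were lower and 0 higher (13 and 2 adjusted over the list alone; median -0.49, camera adjusted p = 6.37e-05; adjusted p = 0.341 with an estimated correlation). Mpeg1 changed by -0.90, Ccr2 by -0.82, C1qc by -0.65 and Timd4, which lost its call under normexp scaling, by -1.70. Stellate cell and fibroblast markers had 4 of 21 lower and 0 higher (6 lower adjusted over the list alone; median -0.35, camera adjusted p = 0.00481; adjusted p = 0.356 with an estimated correlation), among them Vim at -0.66, Pdgfrb at -0.55, Ngfr at -0.54 and Des at -0.34. The list was not called under normexp scaling (-0.14, adjusted p = 0.0828). Its lower count was 2 without AdGFP replicate 1 or AdLeXis replicate 2, 3 or 4, and 5 without AdGFP replicate 3. Pdgfrb lost its call without each array but AdGFP replicate 3, Des, at -0.20 under normexp scaling, was not called without AdGFP replicate 1 or 4 or AdLeXis replicate 2, 3 or 4, nor Ngfr without AdLeXis replicate 2. Endothelial markers did not pass (0 of 20 called by limma, 1 at an unadjusted p under 0.05; median 0.093, camera adjusted p = 0.477).

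Cell cycle genes rose. Of 34 measured, 26 were higher and 1 was lower (28 and 1 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 3.81e-15; adjusted p = 0.272 with an estimated correlation). Cyclin E1, Ccne1, rose by 1.78 (SE 0.15, limma adjusted p = 5.19e-04), Cdc20 by 1.61, cyclin B2, Ccnb2, by 1.45 and the replication helicase gene Mcm6 by 1.45. The higher count was 17 without AdGFP replicate 1 and 14 without AdLeXis replicate 4. The 1 lower member, named after its value was seen, was cyclin D1, Ccnd1, which fell by 1.48 (SE 0.15, limma adjusted p = 0.00118). Targets of p53 rose as well, 11 higher and 2 lower of 20 (11 and 2 adjusted over the list alone; median 0.57, camera adjusted p = 1.40e-05; adjusted p = 0.272 with an estimated correlation). Phlda3 rose by 1.96 (SE 0.12), the cyclin-dependent kinase inhibitor Cdkn1a by 1.60 (SE 0.18; 0.68 to 2.30 over its 3 kept probes) and cyclin G1, Ccng1, by 1.20. Eda2r, not well above background on any AdGFP array, was at least 3.12-fold higher (limma adjusted p = 5.19e-04; log2 difference 0.40 under normexp scaling, still called). The 2 lower members, named after their values were seen, were Plk3 at -0.88, not called under normexp scaling, and the antiproliferative gene Btg2 at -0.44. Btg2 lost its call without each array but AdGFP replicate 2 and AdLeXis replicate 2.

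Immediate early and heat shock genes were mostly lower, 14 of 25 against 2 higher (14 and 2 adjusted over the list alone; median -0.44, camera adjusted p = 6.37e-05; adjusted p = 0.0966 with an estimated correlation). The lower count was 9 without AdGFP replicate 1 or 3 or AdLeXis replicate 1 or 4. Egr2 changed by -1.28 (-0.54 under normexp scaling), Ier3 by -1.05, Gadd45g by -0.66 and Jun by -0.59. The 2 that rose, named after their values were seen, were Gadd45b by 1.23 and Gadd45a by 0.69, the latter not called without AdGFP replicate 1, 2 or 3 or AdLeXis replicate 3 or 4. Circadian genes had 2 higher and 0 lower of 22 (0 by limma adjusted over the list alone, 9 higher and 1 lower at an unadjusted p under 0.05; median 0.25, 0.17 under normexp scaling; camera adjusted p = 0.00729; adjusted p = 0.341 with an estimated correlation), the called ones being Clock at 0.48 and Hlf at 0.35 (0.66 under normexp scaling). Both lost the call under 12 of 21 alternatives, Clock without each array but AdLeXis replicate 1 and Hlf without each but AdGFP replicate 1; Ciart (0.28, limma adjusted p = 0.0534) and Usp2 (0.47, limma adjusted p = 0.0652) did not pass. Each was called under 3 of 21 alternatives: normexp scaling, probes required on all 8 arrays, and cyclic loess for Ciart or a variance model with trend for Usp2.

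Hepatocyte markers were lower under the 75th percentile scaling, 12 of 19 against 1 higher (12 and 1 adjusted over the list alone; median -0.36, camera adjusted p = 1.57e-05; adjusted p = 0.272 with an estimated correlation), but the median was 0.0013 under quantile scaling (adjusted p = 0.952), which gives probes of equal rank equal values, and -0.03 under normexp scaling (adjusted p = 0.697), and -0.23 under cyclic loess (adjusted p = 0.00292). Albumin, Alb, fell by 0.61 (SE 0.09, limma adjusted p = 0.00434) and gave 0.27 under normexp scaling. Its quantile value of 0 was fixed by an equal rank on each array. Ahsg, Serpina1c and Rbp4 changed by -0.58, -0.57 and -0.54, calls lost under both scalings. Foxa2, a liver transcription factor named after its value was seen, rose by 0.60 (SE 0.10, limma adjusted p = 0.00720; 0.38 under normexp scaling). The change followed signal level: of 26 genes with a mean log2 signal over 18, 26 were called lower and 0 higher, and of 104 genes at 17 to 18, 68 were lower and 0 higher. Of 10 spike-in probes, which read transcripts added in equal amounts to each labelling, the brightest differed by -0.34 on the log2 scale, AdLeXis minus AdGFP, and the 6 of middle level averaged -0.10.

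**Figure D3:**
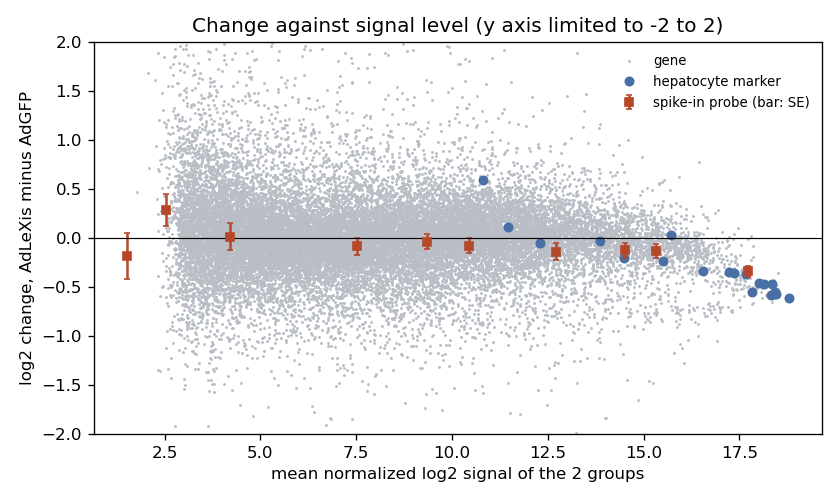
Log2 change, AdLeXis minus AdGFP (y axis, shown from -2 to 2), against the mean normalized log2 signal of both groups (x axis), for each gene (grey), 19 hepatocyte markers (blue) and 10 spike-in probes (red squares with SE). The brightest spike-in stands at -0.34 and the 6 of middle level average -0.10.

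Genes of pericentral hepatocytes had 9 lower and 0 higher of 23 (12 lower adjusted over the list alone; median -0.44, -0.27 under normexp scaling; camera adjusted p = 4.48e-05; adjusted p = 0.341 with an estimated correlation). Gulo changed by -0.68, Cyp2e1 by -0.45 (-0.17 on its other kept probe) and glutamine synthetase, Glul, by -0.39; Cyp2e1 gave 0.030 under quantile scaling and, with Glul, was not called under normexp scaling. The lower count was 4 without AdGFP replicate 1 and 5 without AdGFP replicate 3. Apolipoprotein and lipoprotein genes had 8 lower and 1 higher of 22 (8 and 1 adjusted over the list alone; median -0.25, camera adjusted p = 0.00113; adjusted p = 0.307 with an estimated correlation), and the list was not called under quantile (adjusted p = 0.213) or normexp scaling (0.281). With 1 array left out, the higher count of this list was 1 without AdLeXis replicate 1 and 0 without any other array. Apoa1 changed by -0.73 (-0.44 under quantile scaling) and Apoc1 and Apoa2 by -0.55, the last 2 not called under quantile scaling.

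Xenobiotic metabolism did not pass as a list (median 0.0095, camera adjusted p = 0.453) except under quantile (0.0407) and normexp scaling (0.0307), but 9 of its 35 genes were higher and 3 lower (9 and 5 adjusted over the list alone); the lower count was 1 without AdGFP replicate 1, 5 without AdLeXis replicate 1 and 6 without AdLeXis replicate 3. Cyp2b10 rose from 11.61 ± 0.53 to 14.12 ± 0.32 (SD, n = 4 per group; limma adjusted p = 0.00123), Cyp2b9 by 2.75 (1.44 under normexp scaling), Cyp2c55 by 1.37 and Aldh1b1 by 0.92. Signal shared between closely related Cyp2b copies was not tested. Nearest to no change among its brightest members were Cyp2a4 (0.0095, SE 0.37) and Gstp1 (-0.020, SE 0.33), the latter called without AdGFP replicate 4 (-0.40, limma adjusted p = 0.0267). Growth hormone and sex-biased genes had 6 higher and 4 lower of 32 (7 and 4 adjusted over the list alone), with a median of -0.03, a mean of 0.31 and no call (camera toward higher, adjusted p = 0.796). Hao2, not well above background on any AdGFP array, was at least 3.11-fold higher (limma adjusted p = 0.00204; log2 difference 0.48 under normexp scaling, still called), and the bright Serpina1e and Mup1 changed by -0.61 and -0.55. Serpina1e gave 0.30 under normexp scaling and Mup1 lost its call under quantile and normexp scaling. Cyp2a4 (0.0095) and Cyp2d9 (-0.12) were nearest to no change among its brightest members.

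The acute phase list did not pass (5 higher and 11 lower of 33, 6 and 11 adjusted over the list alone; median -0.21, camera adjusted p = 0.144). Saa3 and Saa4, serum amyloid genes, rose by 1.47 and 1.16, while Il1b changed by -0.89 (-0.45 under normexp scaling) and C3 by -0.51, the last giving 0.0023 and 0.027 under quantile and normexp scaling. Nearest to no change among the brightest members were Mt2 (-0.0087, but 0.34 under quantile scaling) and Hpx (-0.080, SE 0.38), the heme carrier hemopexin, which was called without AdGFP replicate 4 (-0.52, limma adjusted p = 0.0124). The higher count was 2 without AdGFP replicate 2 and 3 without AdGFP replicate 1 or AdLeXis replicate 2 or 4, and the list passed without AdGFP replicate 2 (adjusted p = 0.0465). The bile acid list did not pass either (2 higher and 2 lower of 19, and the same counts adjusted over the list alone; median -0.10, camera adjusted p = 0.382). Cyp39a1 rose by 1.32 and Akr1d1 by 0.45, Akr1c6 fell by 0.57, and the transporter gene Slc10a1 fell by 0.65 (-0.32 on its other kept probe) but gave 0.23 under normexp scaling. Akr1d1 lost its call without each array but AdGFP replicate 1, leaving 1 higher, and 4 were lower without AdLeXis replicate 3. Akr1c6 and Slc10a1 lost their calls under quantile scaling. Abcb4 (0.0090) and Nr1h4 (0.051) were nearest to no change among the brightest members.

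The remaining lists did not pass camera: adipocyte (median 0.45, adjusted p = 0.0569), B cell and plasma cell (-0.23, 0.109), PPARalpha and fatty acid oxidation (0.12, 0.264), cholangiocyte (-0.08, 0.332), periportal (-0.18, 0.382), unfolded protein response (-0.02, 0.465), erythroid (0.08, 0.527), neutrophil (-0.11, 0.741), exocrine pancreas (0.13, 0.744), glucose and glycogen (-0.09, 0.983) and hnRNP family genes (-0.01, 0.983). Members called higher and lower over all genes, and adjusted over the list alone, were 2 and 0 (3 and 0) of 9 for adipocyte, 0 and 1 (0 and 1) of 10 for B cell, 3 and 2 (4 and 2) of 29 for PPARalpha, 0 and 2 (0 and 2) of 14 for cholangiocyte, 3 and 3 (4 and 3) of 22 for periportal, 1 and 2 (1 and 2) of 25 for unfolded protein response, 2 and 0 (2 and 0) of 10 for erythroid, 1 and 0 (1 and 0) of 10 for exocrine pancreas and 3 and 4 (4 and 5) of 21 for glucose and glycogen genes. No member (0) of the neutrophil and hnRNP lists was called by limma in either count; at an unadjusted p under 0.05 they had 1 and 0. The adipocyte list passed under median (adjusted p = 0.0176) and normexp scaling (0.0350), under both other filters, with fry, and without AdGFP replicate 2 or 3 or AdLeXis replicate 1 or 3. PPARalpha genes passed under quantile (0.00618) and normexp scaling (0.00763) and without AdGFP replicate 2 or AdLeXis replicate 1, when 7 were higher. The 3 higher became 1 without AdGFP replicate 1 or 4 or AdLeXis replicate 2, 3 or 4, and the 2 lower became 1 without AdGFP replicate 1, 2 or 3 or AdLeXis replicate 4. Without 1 array the lowest lower counts were 0 for cholangiocyte, 1 for unfolded protein response and 2 for glucose genes, and the lowest higher counts 1 for adipocyte and 1 for erythroid genes. The B cell list passed without AdGFP replicate 3 or AdLeXis replicate 3 or 4. Of the 31 lists, 14 passed, 3 toward higher and 11 toward lower. By fry 15 passed, and 0 passed camera with an estimated correlation. The exact permutation test of list means gave p = 0.0571 for the pericentral and stellate lists, which passed camera. It gave 0.0286, the smallest possible, for the other lists that passed. The xenobiotic, growth hormone and exocrine pancreas lists, which did not pass camera, also had an exact permutation p of 0.0286.

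**Figure D4:**
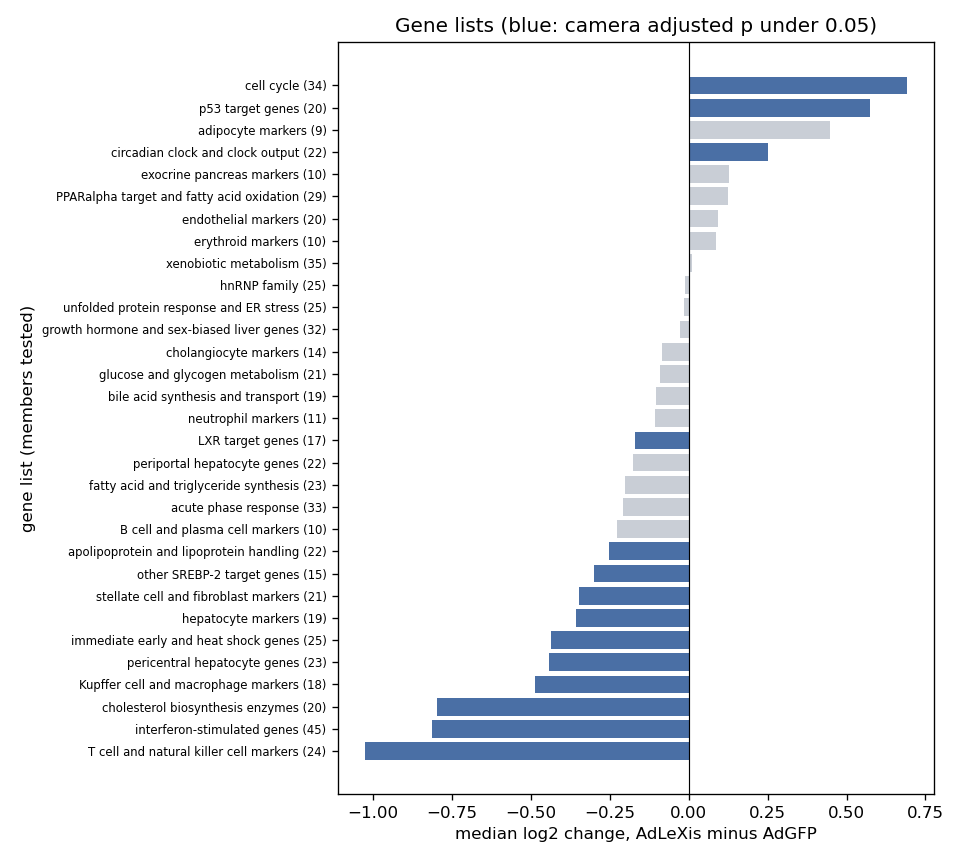
Median log2 change, AdLeXis minus AdGFP (x axis), of the 31 gene lists (y axis, members tested in brackets), blue where camera's adjusted p was under 0.05. T cell and natural killer cell markers lie lowest at -1.02 and cell cycle genes highest at 0.69; the hepatocyte bar of -0.36 is 0.0013 under quantile scaling.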

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

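The tests of explanations in this part were chosen after the results they bear on were seen. In 334 groups of 4 arrays, 21 held an array far from the other 3, where chance gives about 1 in 20 (16.7). AdLeXis replicate 1 and AdGFP replicate 4 were that array 6 times each. In AdLeXis replicate 1 the 75th percentile of intensity was 381 against 437 to 448 on the other AdLeXis arrays, and the level of probe A_30_P01022419 was 9.90 against 10.68 to 10.70. It stood lowest for Wfdc12 (7.50) and highest for Apoe (18.37), Serpina1e (18.21) and C3 (18.28). AdLeXis replicate 4 stood lowest for Pmvk (12.22), Gulo (14.22) and the mean of the LXR list (12.16), and AdLeXis replicate 3 for Cyp2b10 (13.65). AdGFP replicate 1 stood highest for probe A_30_P01024243 (4.12 against 0.46 to 0.77) and Mup1 (18.81) and lowest for Usp2 (11.43). AdGFP replicate 3 stood lowest for Cox6b2 (5.30) and highest for Hmgcs1 (14.76). AdGFP replicate 4 had the highest variation between replicate spots (9.97% against 6.72% to 7.03% on the other AdGFP arrays). It was the 1 array whose extraction status in the file header asked for evaluation. Among the AdGFP arrays it had the lowest means of the p53 (9.40) and pericentral (12.40) lists. It also stood lowest for Hpx (16.58 against 18.32 to 18.37), Gstp1 (16.04 against 17.49 to 17.65) and Cyp2d9 (15.08).

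Of the 35 splits of the 8 arrays into 4 against 4, the real one gave the most changed genes, 4205. The highest of the others gave 1. Missing values were filled by the mean of the real group, which can favour the real split. The fit reported gave 4196. Every other split mixes the groups, so a group difference widens the spread within each side and lowers its count. The test can therefore argue against chance only at 1 in 35, its smallest possible value. It cannot tell treatment from slide row.

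Interferon-stimulated genes and T cell and natural killer cell markers were lower in AdLeXis. The tables argue against scaling as the cause, since over the scalings tried the medians nearest to 0 were -0.78 and -0.71. For the T cell list, the endothelial markers, whose median was 0.093, argue against a general loss of RNA from cells other than hepatocytes. The difference between the 2 list means per array changed by -0.91 (exact permutation p = 0.0286, the smallest possible, n = 4 per group). Macrophage and stellate markers were also lower (medians -0.49 and -0.35), so a loss shared by some of these cells stays open. A response to the foreign GFP protein or to the dose of virus in the control arm cannot be told apart from an effect of LeXis, because 0 groups without virus are among these samples. Slide row and group cannot be told apart either.

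Abundant hepatocyte transcripts were lower in AdLeXis under the 75th percentile scaling. A lower share of hepatocyte RNA would raise the markers of other cells alike. The macrophage median of -0.49 cannot test this, since macrophage markers fell beside the interferon and T cell lists. Medians were 0.093 for endothelial, -0.08 for cholangiocyte, -0.35 for stellate and 0.45 for adipocyte markers. No rise alike was seen, and a lower share of hepatocyte RNA stays open. A candidate explanation is compression of the brightest signals on the brighter AdLeXis arrays. The brightest spike-in probe minus the mean of those of middle level differed by -0.24, AdLeXis minus AdGFP (SE 0.04, exact permutation p = 0.0286, n = 4 per group). The brightest spike-in stood at 17.7 on the log2 scale and the brightest hepatocyte marker at 18.8, and spike-in sequences of this maker derive from an adenovirus gene, so cross-signal from the vectors stays open. A real fall of part of these genes stays open too.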

How the results depend on the processing

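Alternatives were chosen before the results, except cyclic loess, chosen after seeing the data. Slide and scan as a block were not run (1 slide, 1 scan), and with probes required on all 8 arrays the lincRNA region was not tested. Of values that answer the comparison, 378 stayed, 22 lost their call, 10 moved (counts) and 1 reversed (hepatocyte list, quantile scaling). Staying means the same side of the threshold for a test. For a count it means a smaller ratio of the larger to the smaller count than for those said to have moved. Such counts include 6170 genes at an adjusted p under 0.1 and 2800 without AdGFP replicate 1, against 4196. The deposited value table was 1 of the alternatives and repeats the main data. For single genes and uncalled lists, 2924 stayed, 114 lost and 36 gained a call, and 11 reversed. The 4196 genes became 2162 (1086 higher, 1076 lower) with a change of at least 1.5-fold required, since fewer pass; with median scaling 1156 were higher. Without 1 array each the count ran from 2513 to 4117 (1245 to 2084 higher, 1268 to 2033 lower), with fewer samples. With the replicate block it was 3146 (1521 higher, 1625 lower); deviations of same-numbered arrays correlated at 0.013, 0.064, 0.12 and -0.00024 and 3 of 8 arrays correlated best with their own number, so the numbers were not taken as pairing. The lincRNA region ran from 6.99 to 7.83 and the cholesterol list from -0.89 to -0.71 without 1 array each.

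Under quantile scaling the LXR list gave -0.064, apolipoproteins -0.10 and hepatocyte markers 0.0013, and Apoe 0.028, C3 0.0023, Cyp2e1 0.030 and the uncalled Mt2 0.34 reversed. Under normexp scaling these lists gave -0.011, -0.13 and -0.033, stellate markers -0.14, and Apoe 0.082, Alb 0.27, Serpina1e 0.30, C3 0.027, Slc10a1 0.23 and the uncalled Acaca 0.25 reversed; Pls1 gave 0.60 with no filter, where another probe stood for it. The LXR list gave -0.18 under cyclic loess and -0.29 to -0.048 without 1 array each. With an estimated correlation no list was called, by a wider error at the same medians: cholesterol -0.80, other SREBP-2 targets -0.30, LXR -0.17, apolipoproteins -0.25, interferon -0.81, cell cycle 0.69, p53 0.57, immediate early -0.44, circadian 0.25, pericentral -0.44, hepatocyte -0.36, macrophage -0.49, T cell -1.02 and stellate -0.35. For the other changes the cause was not tested. Signal over background limits dim genes: 73 of the higher genes were not well above background on any AdGFP array.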

Other observations

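All groups and tests in this part were chosen after the results were seen. Genes sharing a symbol stem were tested as families with at least 8 members, and 30 of 275 passed camera, 8 toward higher and 22 toward lower; 0 passed with an estimated correlation. Guanylate-binding protein genes (Gbp) fell in 11 of 11 members, with a median of -1.20 (camera adjusted p = 6.08e-08; adjusted p = 0.693 with an estimated correlation), 2 of them in a fixed list, and Gbp2 at -1.20 (-0.79 under normexp scaling). Gimap genes, expressed mainly in lymphocytes, fell in 7 of 8 (median -0.51, camera adjusted p = 5.00e-04; adjusted p = 0.554 with an estimated correlation). Among CC chemokines (Ccl), 8 of 15 fell and 1 rose (median -0.66, camera adjusted p = 0.00116; adjusted p = 0.446 with an estimated correlation), with Ccl2 at -1.53, Ccl3 at -1.23 and Ccl5 at -0.89 (-0.58 under normexp scaling). The immune checkpoint genes Pdcd1, Ctla4 and Icos changed by -1.56, -1.37 and -1.32 (limma adjusted p = 0.00394, 4.43e-04 and 1.67e-04), Ctla4 being well above background on 2 of 4 AdLeXis arrays and at -0.32 under normexp scaling. Cyclin-dependent kinase inhibitor genes and their relatives (Cdkn) rose in 6 of 10 (median 0.43, camera adjusted p = 4.24e-04; adjusted p = 0.481 with an estimated correlation). These 4 families kept their direction under each scaling tried.

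Cdkn1c, an imprinted growth inhibitor, rose by 1.88 (SE 0.29, limma adjusted p = 0.00434) and Ly6d by 2.09 (SE 0.36, limma adjusted p = 0.00688) beside H19 at 3.67, whereas Igf2, the imprinted neighbour of H19, gave -0.10 (SE 0.12, limma adjusted p = 0.620) and the fetal liver gene Afp -0.22 (SE 0.26, limma adjusted p = 0.608).

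Of 15 genes that are higher in female than in male mouse liver, written down from memory after the data were seen, 9 were higher and 0 lower in AdLeXis by limma and 6 did not pass. Enrichment of these genes was not tested. The fixed list of growth hormone and sex-biased genes did not pass (camera adjusted p = 0.796). That list holds both female-biased and male-biased genes, so a test for a shift of the whole list cannot decide this. Cyp2b13 rose by 2.70 (0.80 under normexp scaling), Sult1e1 by 2.20 and Trim24 by 1.15, and Sult2a1, not well above background on any AdGFP array, was at least 2.40-fold higher (limma adjusted p = 0.00512; log2 difference 0.39 under normexp scaling).

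Animals of different sex in the groups are argued against, since the Y-linked genes Ddx3y, Eif2s3y and Uty were well above background on all 8 arrays and the largest difference among them was -0.21, for Uty. Ddx3y gave -0.15 and was called under normexp scaling (-0.25, adjusted p = 0.0404). Scaling stays open as a source of part of the rise of Cyp2b9, Cyp2b10, Cyp2b13, Sult1e1, Sult2a1 and Hao2: their median of 2.72 (2.36 with Sult2a1 and Hao2 at their bounds) was 1.12 under normexp scaling, whose offset shrinks changes of dim probes, and 2.64 or more under the other scalings tried. These 6 genes were chosen because they had risen, and each stayed called as higher under every scaling tried. A loss of the male growth hormone pattern stays a hypothesis that these data do not decide: 12 male-biased genes with a mean log2 signal under 16 had a median of -0.46 (quartiles -0.59 and -0.13), 0 called by limma and 2 lower at an unadjusted p under 0.05, and 3 of 5 brighter ones were lower, in the range where bright genes fell in general. As first set, a median above -0.5 was to count against it; the rule was changed to the quartiles after the value was seen.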
